A study of Mus musculus with 36 samples.

How the data were processed

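RNA of dorsal root ganglion and dorsal spinal cord was measured by sequencing in 36 libraries, 18 per tissue. Per the labels' protocols, RNA was extracted with a spin column kit (RNeasy Plus Universal Mini), checked on a Qubit fluorometer and a Bioanalyzer, and made into stranded poly(A) libraries with a TruSeq kit from 1 µg of RNA each. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 and RSEM were used with mouse build GRCm38. The roles and order of the tools, the versions of HISAT2 and RSEM, and the annotation were not given in the sources used here.

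The raw table deposited by the authors held expected counts, that is, reads per gene as estimated by RSEM, not whole numbers, for 55487 genes, and 55141 of these had a name and a place in GENCODE M21. The column of library E1 in the same deposited table had the unit other in the record of the files, since 9150 of its cells were written with decimal commas and 1 cell held a letter. Its commas were read as points, and the lost cell was restored to 1780.86 from the normalised table and the factor of that column. The normalised table deposited by the authors held signal values, each column being the raw column times 1 TMM (trimmed mean of M values) factor, for 52999 genes. The 2488 genes found only in the raw table were kept for the main tests. Expected counts were rounded to whole numbers for edgeR and DESeq2. All columns with values per sample were used, the normalised ones only in an alternative test and in the repair of that column.

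Libraries were grouped by tissue, genotype and injury as the labels gave them, in 8 groups of 5 libraries (naive) or 4 libraries (injured). Naive libraries A2 and A4 of DRG were titled wild type, while their genotype field said knockout, and the field was followed. An alternative without both was set before the data were examined. Letters and numbers of the libraries came from the titles. Column names carried a number that paired DRG and cord libraries. It was read here as an animal number, which the labels did not state, and was used only to relate tissues. Whether each library came from a separate animal was not stated in the labels.

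Depth was 21.34 to 27.27 M estimated reads per library, by group 22.69 to 27.27 in naive wild-type DRG, 22.34 to 24.56 in injured wild-type DRG, 22.11 to 24.78 in naive knockout DRG, 21.44 to 24.01 in injured knockout DRG, 22.5 to 24.76 in naive wild-type cord, 22.59 to 23.89 in injured wild-type cord, 21.34 to 23.12 in naive knockout cord and 22.39 to 22.88 in injured knockout cord. Libraries of the same group differed by a mean chi-square per gene of 2.76 to 70.44, where 1 would be sampling noise alone. The common biological coefficient of variation was 0.131 in DRG and 0.0744 in cord.

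The following choices were made before the data were examined. Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3, with 18 libraries in 4 groups and 14 residual degrees of freedom, TMM factors, filterByExpr over the 4 groups and robust quasi-likelihood F tests. Genes left after the filter numbered 19496 in DRG and 18843 in cord. The 10 comparisons were SNI against naive within each genotype, knockout against wild type within naive and within injured libraries, and the interaction of genotype and injury, in each tissue. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and no fold threshold was used. Standard errors were the log2 fold change divided by the square root of the F statistic. CPM used TMM library sizes.

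Gene lists were fixed before the data were examined, 27 in number, and tested by camera of limma 3.58.1 with the preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Those reported were neuronal injury genes, nociceptor genes, potassium channels, general neuronal genes, macrophage, microglia, neutrophil, T cell, B cell, chemokine and cytokine, antigen presentation, interferon response, astrocyte and satellite glia, Schwann cell and peripheral myelin, oligodendrocyte, endothelial, fibroblast and extracellular matrix, blood, skeletal muscle, motor neuron, unfolded protein response, opioid, mitochondrial respiratory chain, cell cycle and immediate early genes. Some genes and lists are not reported here. Lists with fewer than 3 genes tested were left out. Alternatives were a correlation estimated from the data and, for genotype comparisons, an exact permutation test of the list score of each library, the mean of log2(CPM + 1) over its members. That test reaches no p under 0.0286 for 4 against 4 or 0.00794 for 5 against 5 libraries. Counts adjusted over the list alone used the p values of list members only.

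Genes were named by a rule set before the data were examined. Named were the 6 largest rises and the 6 largest falls per comparison among called genes with a mean log2 CPM of at least 1 and no overlap between libraries of the groups compared, and up to 3 called members of each list with the lowest adjusted p. Predicted genes were counted and not named, apart from a pair in the interaction. Fold changes against levels near 0 were given as levels or beside them.

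Alternatives set before the data were examined were median-ratio (RLE) factors in place of TMM, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared (or all 36 libraries for the interaction), limma-trend on the authors' normalised table, the letter of the title as a block, leaving out A2 and A4, and leaving out each library in turn. Chosen after seeing the data were fits without C1, E3 and F3, without A5, B5, E6, F5 and F6, and with the blood score of each library as a covariate. Size factors of both kinds differed by at most 0.0131 in log2 between groups. Chance was tested by regrouping the libraries of a comparison, in 35 ways for 4 against 4 and in 100 drawn ways for the others. The tests were checked on simulated data with known changes. At a log2 change of 1, edgeR called 82.5% of changed genes for injury in wild-type DRG, 62.7% for genotype in injured DRG and 68.2% for the DRG interaction, and 92.1%, 85.1% and 75.4% for the same 3 tests in cord. At 0.5 the interaction call rate was 16.4% in DRG and 64.6% in cord. These rates are rough, since each came from 1 draw with genes simulated independently and no shift shared by the genes of a library. The cord interaction rate even lay above those of the simpler cord tests (47.8% to 63.6%). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads were not used here, so mapping was not repeated and variants were not called.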

Results

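The series held 36 RNA sequencing libraries of mice, wild type or knockout, taken from dorsal root ganglion (DRG) and dorsal spinal cord. Each tissue had 5 naive libraries and 4 libraries after spared nerve injury (SNI) per genotype. Xist, the transcript of the inactive X chromosome, was present in every library (405.5 to 984.9 CPM, counts scaled by library size), so all came from females. Depth ran from 21.34 to 27.27 M estimated reads. Values after ± were standard errors for log2 fold changes and standard deviations for CPM, and a gene was called when its adjusted p was under 0.05 over all genes tested. The p values measured the spread between libraries, because the labels did not state that each library came from a separate animal.

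Injury of the sciatic nerve branches switched on the known axon injury program in wild-type DRG (4 SNI against 5 naive libraries). The regeneration gene Sprr1a went from 0.185 ± 0.0931 to 515 ± 137 CPM (adjusted p = 7.91e-16), and the neuropeptide genes Npy and Crh from 0.268 ± 0.214 to 125 ± 16.9 CPM and 0.0541 ± 0.0337 to 9.13 ± 3.62 CPM. The endopeptidase gene Ecel1 went from 0.316 ± 0.14 to 81 ± 10.5 CPM. Anxa10, an annexin, rose from 0.025 ± 0.0388 to 13.4 ± 1.42 CPM, and the lipase gene Lipn from 0.0501 ± 0.0476 to 12.5 ± 1.29 CPM. The transcription factor gene Atf3, a marker of axotomized neurons, rose from 5.7 ± 0.684 to 346 ± 43.9 CPM (log2 fold change 5.92 ± 0.11, adjusted p = 2.06e-17). Gal, which encodes galanin, rose from 13.3 ± 1.42 to 1109 ± 90.4 CPM (6.38 ± 0.09, adjusted p = 2.01e-19). Flrt3, a gene of axon guidance, rose by 3.54 ± 0.05, adjusted p = 2.01e-19. All 23 measured members of the neuronal injury list rose, with a median log2 fold change of 2.94. The list held with either treatment of correlation between genes (camera adjusted p = 4.78e-268 with the preset value and 4.34e-08 with an estimated correlation).

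Many nociceptor and potassium channel genes fell in injured wild-type DRG. Over all genes, the largest falls above the expression floor were in Dnah6, a dynein of cilia (-1.83 ± 0.20, adjusted p = 1.56e-06), the cell adhesion gene Cntn5 (-1.56 ± 0.21), and Calb2, which encodes calretinin (-1.38 ± 0.20). The delta opioid receptor gene Oprd1 (-1.36 ± 0.21, adjusted p = 8.21e-05), the nicotinic receptor gene Chrnb3 (-1.23 ± 0.26) and the serotonin receptor gene Htr3a (-1.22 ± 0.08, adjusted p = 3.99e-09) fell with them. Of 17 nociceptor genes 11 fell, 12 when adjusted over the list alone. Among them were Tac1 for substance P (-0.77 ± 0.08), the irritant channel Trpa1 (-0.76 ± 0.08) and Calcb for a calcitonin gene-related peptide (-0.50 ± 0.07). Of 16 potassium channel genes 8 fell and 1 rose, 11 and 1 when adjusted over the list alone. The clearest falls were in Kcnb2 (-0.84 ± 0.07, adjusted p = 3.43e-08), Kcns3 (-0.93 ± 0.09) and Kcnt1 (-0.74 ± 0.08). Both lists were called with camera (adjusted p = 4.01e-06 each) and neither was with an estimated correlation (adjusted p = 0.238 for nociceptor genes and 0.381 for potassium channels). Among 6 opioid genes the nociceptin receptor gene Oprl1 fell (-1.16 ± 0.11) and Pomc rose (1.29 ± 0.20), with 4 falls and 2 rises and the list not called (0.0857). Of 12 general neuronal genes 4 rose, such as Stmn2 (0.96 ± 0.07) and Tubb3 (0.83 ± 0.11), and 3 fell, such as Snap25 (-0.54 ± 0.08), so the neuronal falls were not a loss of all neuronal transcripts (list adjusted p = 0.601).

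Macrophage genes rose in injured wild-type DRG. Of 18 measured members 17 rose, 18 when adjusted over the list alone, with a median of 1.36. Csf1r, the receptor gene through which Csf1 from injured neurons acts on macrophages, went from 45 ± 10.7 to 120 ± 22.6 CPM (1.41 ± 0.17, adjusted p = 4.67e-06). Ms4a7 (2.11 ± 0.24) and the complement gene C1qc (1.66 ± 0.20) rose as well. Of 14 microglia genes, which resident macrophages of the ganglion share in part, 10 rose (11 when adjusted over the list alone, median 1.09). Fcrls (2.01 ± 0.19) and Cx3cr1 (1.41 ± 0.16) were among them. Of 17 chemokine and cytokine genes 9 rose (10 when adjusted over the list alone, median 0.83), including Il6 (0.284 ± 0.0869 to 1.16 ± 0.129 CPM), Ccl12 (1.98 ± 0.26) and Ccl8 (0.966 ± 0.899 to 14.5 ± 3.14 CPM). The camera adjusted p was 2.29e-12 for macrophage, 3.33e-07 for microglia and 0.000627 for chemokine and cytokine genes. With an estimated correlation the adjusted p was 0.238, 0.238 and 0.492. Blood genes had a median of -0.92 without any member passing (adjusted p = 0.315), so added blood did not accompany the rise.

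In injured wild-type DRG 9 of 17 genes of the unfolded protein response rose (9 when adjusted over the list alone), with a median of 0.15. They included Chac1, a gene of glutathione breakdown (2.43 ± 0.17, adjusted p = 3.27e-09), Asns (0.42 ± 0.04) and Atf4 (0.48 ± 0.06). That list was called (adjusted p = 0.000422) and was not with an estimated correlation (0.238). Itpr1, an inositol trisphosphate receptor gene, rose (0.89 ± 0.07) with Pgrmc1 (0.15 ± 0.05), and the NMDA receptor gene Grin1 fell (-0.56 ± 0.17). Satellite glia genes went both ways, with 4 rises and 2 falls of 11 (0.312). The risers included Aldh1l1 (1.14 ± 0.12), Glul (0.53 ± 0.06) and Gfap (1.26 ± 0.18). Of 16 interferon response genes 6 rose, such as Mx1 (1.15 ± 0.26), without a call of the list (0.162). Of 10 immediate early genes 3 rose, Btg2 (0.83 ± 0.12), Fos (0.69 ± 0.18) and Arc (0.53 ± 0.18). Single members rose or fell in the neutrophil (Ly6g, 1.73 ± 0.40), T cell (Cd4, 1.26 ± 0.27) and motor neuron lists (Isl1, -0.56 ± 0.07, and Slc5a7, 0.55 ± 0.12). Of 12 matrix genes 2 rose, Timp1 (1.27 ± 0.24) and Postn (0.36 ± 0.07), and 2 of 19 respiratory chain genes fell, Sdha (-0.20 ± 0.06) and Uqcrc2 (-0.23 ± 0.08). Skeletal muscle genes such as Acta1 varied between libraries (5.46 ± 5.02 to 1.05 ± 0.849 CPM), and 3 of 7 fell, 7 when adjusted over the list alone (list 0.152). B cell, antigen presentation, Schwann cell, endothelial and cell cycle genes had no member that passed.

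In total 4864 of 19496 genes tested changed in injured wild-type DRG, 2465 up and 2399 down, of which 695 rose and 125 fell more than 2-fold. Unadjusted p was under 0.05 for 6861 genes, against 975 by chance. With only these 9 libraries in the fit the count was 3216.

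In knockout DRG injury raised the axon injury genes too (4 SNI against 5 naive libraries). Sprr1a went from 0.341 ± 0.2 to 610 ± 52.8 CPM (adjusted p = 8.05e-16), Npy from 0.222 ± 0.166 to 136 ± 21.5 CPM, Crh from 0.0164 ± 0.0368 to 13.5 ± 1.61 CPM, and Lipn from 0.0257 ± 0.0376 to 16.9 ± 2.42 CPM. Anxa10 went from 0.0624 ± 0.0397 to 18.8 ± 1.39 CPM, and the cholecystokinin receptor gene Cckbr from 0.116 ± 0.07 to 22.2 ± 3.26 CPM. Gal went from 10.4 ± 0.818 to 1789 ± 71.2 CPM (7.43 ± 0.10, adjusted p = 3.05e-20), Atf3 rose by 5.69 ± 0.11 and Flrt3 by 3.96 ± 0.05. The largest falls were in Mafa, a transcription factor gene of touch neurons (-1.69 ± 0.22, adjusted p = 1.11e-05), Dnah6 (-1.65 ± 0.20) and Calb2 (-1.64 ± 0.20). Cdkl4 (-1.63 ± 0.18), the neurotensin receptor gene Ntsr2 (-1.58 ± 0.27) and Vstm2b (-1.38 ± 0.19) came next. All 23 neuronal injury genes rose again (median 2.62, camera adjusted p = 8.87e-237 and 8.96e-08 with an estimated correlation).

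Of 17 nociceptor genes 12 fell in injured knockout DRG (13 when adjusted over the list alone), among them Tac1 (-0.69 ± 0.08), the cold channel gene Trpm8 (-0.97 ± 0.16) and Calca (-0.36 ± 0.07). Of 16 potassium channel genes 12 fell (13 when adjusted over the list alone), led by Kcns3 (-0.95 ± 0.09), Kcnb2 (-0.63 ± 0.07) and Kcnt1 (-0.61 ± 0.08). The nociceptor list was called at adjusted p = 1e-04 and the potassium channel list at 1.88e-06, and both had adjusted p = 0.489 with an estimated correlation. Oprl1 (-1.07 ± 0.11), Oprd1 (-1.32 ± 0.20) and the kappa receptor gene Oprk1 (-0.85 ± 0.16) fell, and 2 opioid genes rose (list adjusted p = 0.19). All 18 macrophage genes rose (median 1.73, adjusted p = 1.72e-14, 0.436 with an estimated correlation). Csf1r went from 27.1 ± 4.52 to 87.4 ± 12.8 CPM, and Ms4a7 (2.44 ± 0.26) and the scavenger receptor gene Msr1 (1.90 ± 0.21) rose. Of 14 microglia genes 10 rose and 1 fell (11 and 1 when adjusted over the list alone, median 1.17). Of 17 chemokine and cytokine genes 8 rose (10 when adjusted over the list alone, median 0.91), with Il6 (2.10 ± 0.24), Ccl12 (2.05 ± 0.30) and Ccl9 (1.35 ± 0.23). Their adjusted p was 1.16e-05 and 0.00742, and 0.436 and 0.838 with an estimated correlation.

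Of 17 unfolded protein response genes 8 rose in knockout, with Chac1 (1.55 ± 0.16) and Asns (0.44 ± 0.04), and the list was not called (adjusted p = 0.0673). Itpr1 rose (1.08 ± 0.07), and Grin1 (-0.77 ± 0.17) and the potassium channel gene Kcnh2 (-0.74 ± 0.19) fell. The neutrophil gene Ly6g rose (0.168 ± 0.123 to 3.2 ± 0.278 CPM) with Cxcr2 (1.06 ± 0.23), and 3 of 10 cell cycle genes rose, Top2a (1.34 ± 0.33), Ccnb1 (1.11 ± 0.32) and Aurkb (1.03 ± 0.34). Blood genes had a median of 0.61 here without any member passing (adjusted p = 0.615), and over 18 DRG libraries, within groups, neutrophil and cell cycle scores followed the blood score (r = 0.935 and 0.864). Of 19 respiratory chain genes 7 fell, such as Sdha (-0.32 ± 0.06) and Atp5a1 (-0.30 ± 0.07), with the list at 0.115. In all, 5549 genes changed, 2949 up and 2600 down, with 906 rises and 129 falls of more than 2-fold and 7442 genes at unadjusted p under 0.05.

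The injury responses of both genotypes ran parallel in DRG. Rises were shared by 2011 genes, such as Sprr1a, Gal and Csf1r, where 373 would be shared by chance, and falls by 1635, such as Tac1 and Oprl1, where 320 would be. Opposite calls were made for 2 genes. Over the 6765 genes called in either genotype the slope of knockout on wild-type log2 fold change was 0.974, the correlation 0.928, and 96.7% had the same sign.

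**Figure D1:**
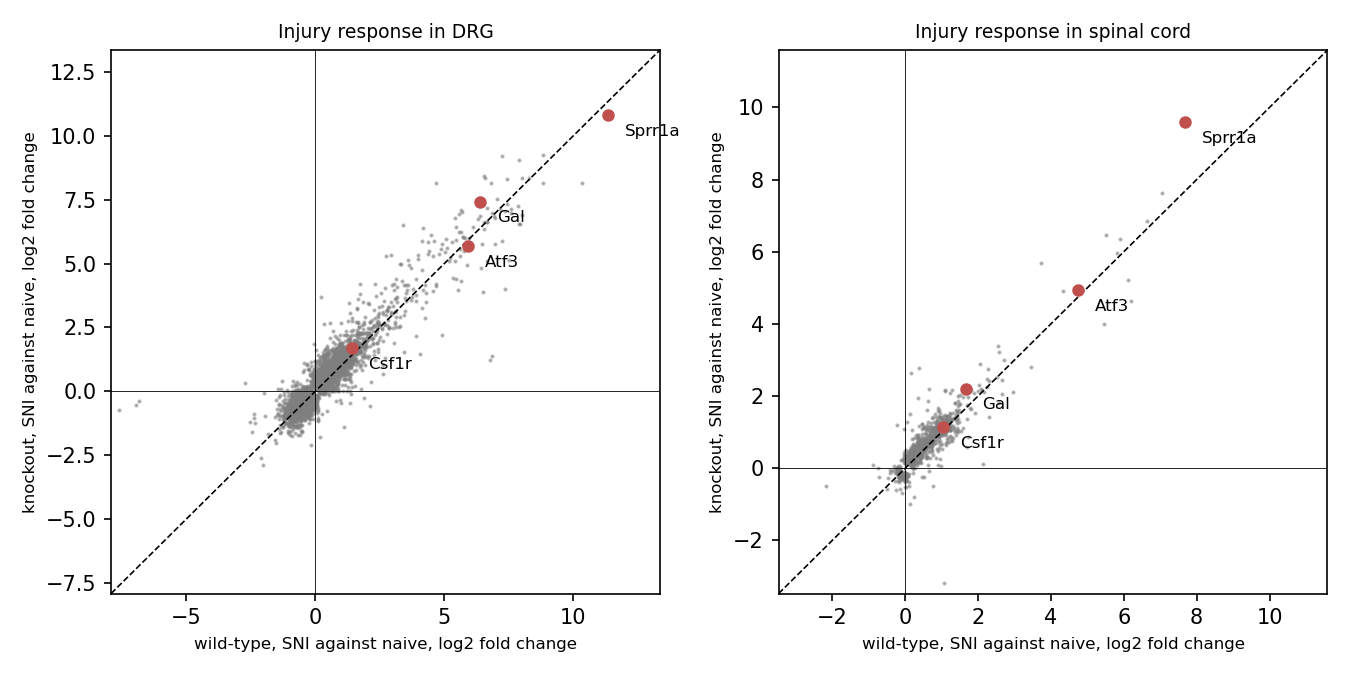
Log2 fold change after SNI in knockout (vertical) against wild type (horizontal), with DRG at left and spinal cord at right. Points are genes called in either genotype, the dashed line marks equal change, and the slopes were 0.974 in DRG and 0.984 in cord.

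The injury response differed between genotypes for 5 of 19496 DRG genes (interaction test, edgeR, 18 libraries). Gal carried the clearest difference. It rose further in knockout, to 1789 ± 71.2 CPM (1693 to 1861) against 1109 ± 90.4 CPM (1031 to 1232) in wild type, from 10.4 and 13.3 CPM in naive libraries (difference in log2 fold change 1.05 ± 0.113, adjusted p = 0.000549). Cyp4b1, a cytochrome P450 gene, reached 23.3 ± 1.83 CPM in injured knockout and 11.6 ± 1.42 CPM in injured wild type from 1.43 and 1.77 CPM (1.33 ± 0.188, adjusted p = 0.0128). Flrt3 reached 194 and 195 CPM after injury from 12.4 CPM in knockout and 16.8 CPM in wild type, so its larger rise (0.43 ± 0.07, adjusted p = 0.0255) came from a lower naive level. The other 2 were predicted genes, named after their values had been seen, C130060K24Rik (0.0678 to 0.971 CPM in knockout and 1.12 to 1.32 CPM in wild type, adjusted p = 0.0128) and 9430062P05Rik (-1.5 ± 0.241, adjusted p = 0.0279). Unadjusted p was under 0.05 for 1160 genes, and DESeq2 called 25. The count of 5 was 1 without F2, 2 without A4 and 3 without A2, A3, E2, E4 or F4. No member of the macrophage, chemokine or nociceptor lists differed in its response, and 1 of 17 unfolded protein response genes moved lower with injury in knockout than in wild type when adjusted over the list alone. As lists, blood (median 1.5, adjusted p = 0.00025), neutrophil (0.96, 0.00026), macrophage (0.30, 0.0342), skeletal muscle (1.56, 0.0422), general neuronal (-0.17, 0.00596) and unfolded protein response genes (-0.04, 0.017) were called. None was with an estimated correlation (adjusted p = 0.869, 0.921, 0.921, 0.921, 0.921 and 0.897). With the blood score in the fit, chosen after the results were seen, the medians of blood (-0.00594), neutrophil (-0.52), macrophage (-0.14) and general neuronal genes (0.085) changed sign.

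**Figure D2:**
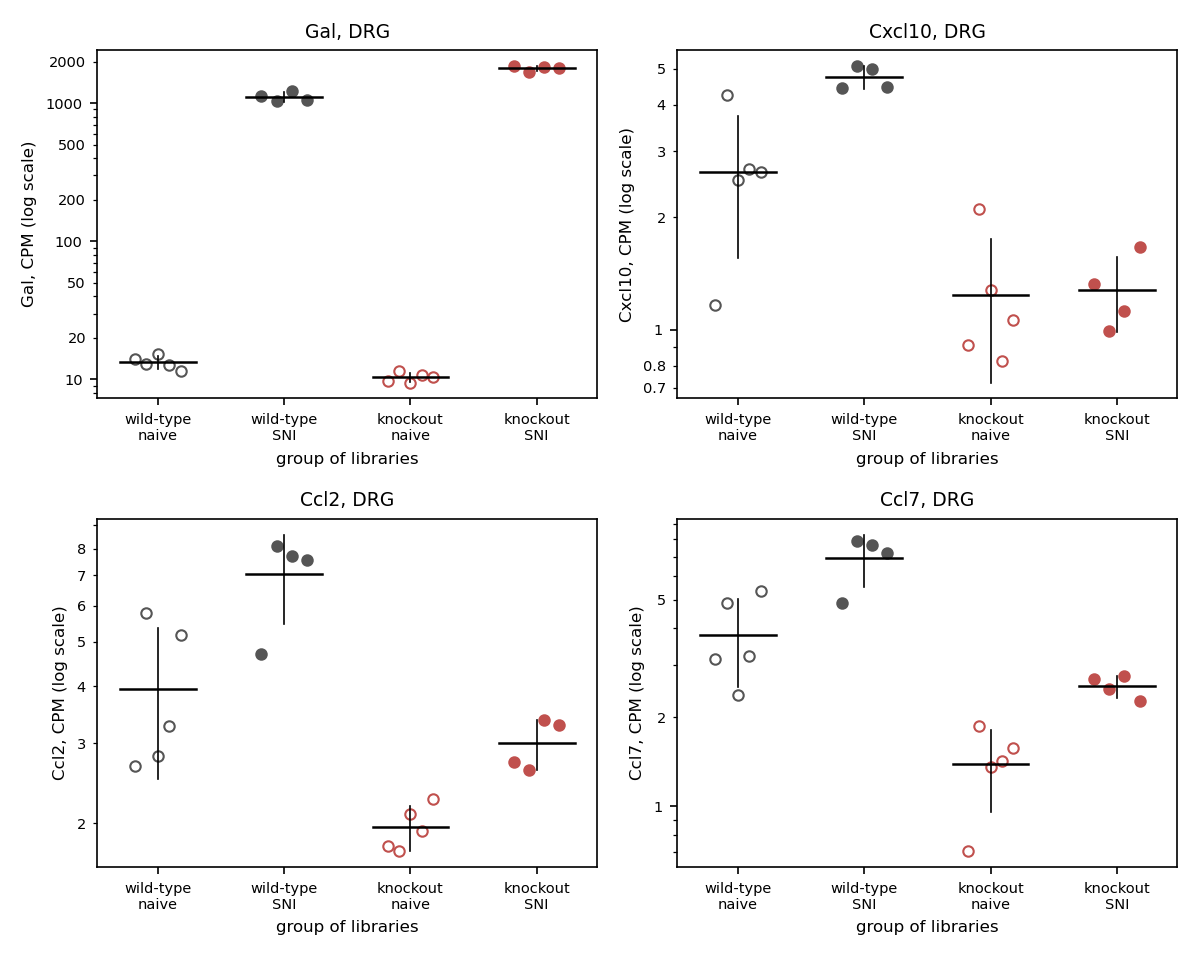
Gal, Cxcl10, Ccl2 and Ccl7 in DRG libraries, in CPM on log scales, by group. Points are libraries, horizontal bars are means and vertical bars standard deviations, and injured knockout libraries stand above wild type for Gal (1789 against 1109 CPM) and below it for Cxcl10 (1.28 against 4.74 CPM).

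Naive knockout DRG held less of many immune transcripts than naive wild-type DRG (5 against 5 libraries). The monocyte attractant genes Ccl7 (1.39 ± 0.43 against 3.79 ± 1.26 CPM, log2 fold change -1.46 ± 0.24, adjusted p = 0.000536) and Ccl2 (1.96 ± 0.22 against 3.94 ± 1.44 CPM, -1.01 ± 0.21, adjusted p = 0.00374) were lower in knockout, and so was Csf1r (27.1 ± 4.52 against 45 ± 10.7 CPM, -0.73 ± 0.16, adjusted p = 0.00521). The phagocytic receptor gene Trem2 (-1.45 ± 0.26), Tyrobp (-0.99 ± 0.21) and Cx3cr1 (-0.80 ± 0.16) followed. The immunoglobulin gene Ighm (-1.30 ± 0.19, adjusted p = 0.000176), the neutrophil genes Ly6g (0.168 ± 0.123 against 1.25 ± 1.1 CPM), Mmp9 (-2.01 ± 0.48) and Camp (-1.94 ± 0.48) were lower too. So was the proliferation gene Mki67 (5.26 ± 1.11 against 18 ± 11.4 CPM, -1.78 ± 0.34, adjusted p = 0.00209). Hemoglobin moved with them, with Hba-a1 at 202 ± 80.8 against 796 ± 515 CPM (-1.98 ± 0.44, adjusted p = 0.00574) and Hba-a2 at -2.32 ± 0.49. By list, 11 of 12 neutrophil (12 when adjusted over the list alone, median -1.88), 11 of 18 macrophage (16, -0.67), 6 of 14 microglia (7, -0.49, with 1 higher when adjusted over the list alone) and 6 of 17 chemokine and cytokine genes (7, -0.74) were lower. So were 2 of 9 B cell (3, -0.76), 8 of 10 cell cycle (-0.84) and 5 of 5 blood genes (-2.13), and none of these was higher over all genes.

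The camera adjusted p was 0.000169 for neutrophil and macrophage, 0.00151 for cell cycle, 0.0018 for blood, 0.00349 for chemokine and cytokine and 0.0455 for microglia and B cell genes. With an estimated correlation the adjusted p was 0.796 for all but B cell genes, which had 0.81. In the exact permutation test of list scores between libraries, neutrophil, blood and cell cycle genes had adjusted p = 0.0429, microglia 0.0536, macrophage 0.0857, chemokine 0.117 and B cell genes 0.214. Of 12 matrix genes 4 were lower, among them Lum (-0.92 ± 0.18), Dcn (-0.69 ± 0.20) and Postn (-0.31 ± 0.06), with adjusted p = 0.0126 and 0.796 with an estimated correlation. The vessel genes Tek (-0.57 ± 0.13), Tie1 (-0.45 ± 0.12) and Pecam1 (-0.34 ± 0.10) were lower in a list of 9 with 4 falls that was not called (0.166). With the blood score in the fit, chosen after the results were seen, the medians of neutrophil (0.15), B cell (0.64) and matrix genes (0.14) changed sign. Camp (0.12) and Pecam1 (0.012) changed sign too. Schwann cell genes held level, with 1 of 11 higher (Egr2, 0.53 ± 0.11).

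Some neuronal transcripts were higher in naive knockout DRG. Of 12 general neuronal genes 7 were higher (9 when adjusted over the list alone, median 0.31), such as the neurofilament gene Nefm (0.74 ± 0.20, adjusted p = 0.0153), Uchl1 (0.38 ± 0.10) and Snap25 (0.29 ± 0.08). Also 5 of 16 potassium channel genes were higher (median 0.21), among them Kcnc1 (0.76 ± 0.16) and Kcna1 (0.54 ± 0.17). The general neuronal list had adjusted p = 0.000715 and the potassium channel list 0.0126, both 0.796 with an estimated correlation and 0.0429 in the exact permutation test. Over 18 DRG libraries, within groups, the general neuronal score fell as the blood score rose (r = -0.721, rho = -0.655, permutation p adjusted over 7 relations 0.00681, r = -0.653 without C1 and A2). Of 17 nociceptor genes 1 was higher and 4 lower (3 and 4 when adjusted over the list alone, median 0.17, list adjusted p = 0.927). Among the lower were Trpa1 (-0.50 ± 0.08, adjusted p = 0.000239), Calcb (-0.38 ± 0.07) and the mu opioid receptor gene Oprm1 (8.79 ± 1.1 against 14.3 ± 1.73 CPM, -0.70 ± 0.14, adjusted p = 0.00274), while Oprk1 was higher (0.51 ± 0.14). Of 23 injury genes 6 were higher and 2 lower, with Gal at -0.36 ± 0.08, Flrt3 at -0.44 ± 0.05 and Hspb1 at 0.49 ± 0.11. The water channel gene Aqp4 (0.80 ± 0.10, adjusted p = 1.69e-05), Glul (0.39 ± 0.06) and Gja1 (0.32 ± 0.08) of satellite glia were higher. Of 17 unfolded protein response genes 3 were higher and 1 lower, among them Dnajb9 (0.22 ± 0.07), Xbp1 (-0.25 ± 0.08) and Chac1 (0.55 ± 0.17). Tmem97, a membrane protein gene, was lower (-0.26 ± 0.05, adjusted p = 0.00335), with Itpr2 (-0.65 ± 0.19), and Grin1 was higher (0.54 ± 0.16). Itpr2 changed sign with the blood score in the fit (0.056), chosen after the results were seen. Of 19 respiratory chain genes 3 were higher and 7 lower (3 and 10 when adjusted over the list alone, median -0.20, list adjusted p = 0.372). Cox7b was among the lower (-0.84 ± 0.15) and Sdha among the higher (0.24 ± 0.06).

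The largest single differences in naive DRG were in genes with little known tie to pain. Cwc22, a splicing factor gene, was higher in knockout (951 ± 65.9 against 137 ± 78.1 CPM), as were the motor protein gene Myo5b (12.4 ± 0.656 against 2.09 ± 0.88 CPM, 2.55 ± 0.21, adjusted p = 2.08e-07), the interleukin 36 gene Il1f9 (2.13 ± 0.18) and the peptide transporter gene Slc15a2 (1.76 ± 0.18). The pseudogenes Got2-ps1 (9.03 ± 1.05 against 0.0176 ± 0.0395 CPM) and Rpl17-ps5 (64 ± 8.63 against 7.29 ± 9.94 CPM) were higher as well. Near-absent in knockout were Vcp-rs (0.257 ± 0.362 against 282 ± 46.2 CPM), Tpm3-rs7 (0.237 ± 0.0709 against 25.6 ± 13.4 CPM), and Rps24-ps3 (0.209 ± 0.156 against 41.3 ± 22.2 CPM), with Rps19-ps6 (0.246 ± 0.184 against 9.36 ± 5.32 CPM), Hmga1b (0.211 ± 0.0481 against 7 ± 1.6 CPM) and the histone gene Hist1h2al (0 against 4.65 CPM). These resemble other genes in sequence, so reads may have been assigned between copies, as for Vcp, which was higher (1.67 ± 0.12, adjusted p = 3.76e-08) while Vcp-rs was lower. The chemokine gene Ccl19 was lower (1.08 ± 0.241 against 12.2 ± 1.7 CPM, -3.50 ± 0.14, adjusted p = 1.33e-11). In total 5506 genes differed, 2494 higher and 3012 lower in knockout, with 156 and 582 of them more than 2-fold and 8331 at unadjusted p under 0.05. The count was 2626 without A2 and A4, 3032 without C1, the wild-type library richest in blood, 3084 without A3 and 3248 without A2, and 532 with the blood score of each library in the fit. With that score, a fit chosen after the results were seen, Ccl7, Ccl2, Csf1r, Mki67, Oprm1 and Hba-a1 were not called (adjusted p = 0.194, 0.523, 0.568, 0.677, 0.444 and 0.981).

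Injured knockout DRG held less of a few chemokines than injured wild-type DRG (4 against 4 libraries). Cxcl10, which draws T cells, was lower (1.28 ± 0.292 against 4.74 ± 0.344 CPM, -1.89 ± 0.30, adjusted p = 0.000692), as were Ccl7 (2.55 ± 0.222 against 6.92 ± 1.39 CPM, -1.44 ± 0.25, adjusted p = 0.00145) and Ccl2 (3 ± 0.378 against 7.03 ± 1.56 CPM, -1.23 ± 0.23, adjusted p = 0.00251). Of 17 chemokine and cytokine genes 4 were lower, 5 when adjusted over the list alone, and 12 did not pass in either count (median -0.51). The list was called (camera adjusted p = 6.3e-05), had adjusted p = 0.844 with an estimated correlation, and its score had the smallest exact permutation p that 4 against 4 libraries allow, 0.0286 (adjusted 0.331). Trem2 (-0.91 ± 0.24, adjusted p = 0.0347) and Cx3cr1 (-0.62 ± 0.17) were lower, while no macrophage gene passed over all genes (2 lower when adjusted over the list alone). Ifit3 (-0.86 ± 0.20, adjusted p = 0.0155) was the only interferon response gene that passed, and it was lower. Of 8 T cell genes 1 was lower, Cd4 (-1.35 ± 0.29), and 1 higher (median -0.013, list adjusted p = 0.931). The blood list was not called in injured DRG (median -0.56, adjusted p = 0.385). Its median lay as low as that of the chemokine list, so equal blood content was not shown.

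Gal, the galanin gene, was higher in injured knockout DRG (0.69 ± 0.08, adjusted p = 2.15e-05) and the neurotensin gene Nts lower (212 ± 17.3 against 357 ± 97 CPM, -0.75 ± 0.20, adjusted p = 0.0354), and no other of 23 injury genes passed. Xbp1, a transcription factor gene of the unfolded protein response, was lower (-0.34 ± 0.09, adjusted p = 0.0332), and so was Tmem97 (-0.30 ± 0.06, adjusted p = 0.0066). Aqp4 (0.69 ± 0.11) and Glul (0.36 ± 0.07) were higher and the vessel gene Cldn5 was lower (-0.56 ± 0.13). Microglia (0.00585, median -0.42), macrophage (0.00598, -0.43), respiratory chain (0.0223, -0.20), interferon response (0.0263, -0.31), cell cycle (0.0263, -0.56) and potassium channel lists (0.0326, 0.14) were called, each with adjusted p = 0.844 with an estimated correlation. The potassium channel median turned to -0.026 without C1, E3 and F3. In injured wild-type DRG E3 and F3 stood apart from E1 and F1, with macrophage scores of 5.32 and 5.244 against 4.506 and 4.881 and general neuronal scores of 9.015 and 8.92 against 9.491 and 9.385. The naive differences in Myo5b (2.05 ± 0.24), Il1f9 (1.82 ± 0.20), Cwc22 (2.16 ± 0.49) and Ccl19 (-2.90 ± 0.16) were present after injury too, with the olfactory receptor gene Olfr920 (1.57 ± 0.16) and Slitrk6 (1.52 ± 0.28) also higher. Got2-ps1 was higher (7.98 ± 1.05 against 0.117 ± 0.184 CPM), and Rpsa-ps10 (0.367 ± 0.264 against 108 ± 52.4 CPM) and Vcp-rs (0.356 ± 0.308 against 300 ± 64.9 CPM) were near-absent in knockout. In total 994 genes differed, 466 higher and 528 lower, with 4190 at unadjusted p under 0.05. Of these, 341 were higher and 457 lower in naive libraries too. The count was 649 with only the 8 injured libraries in the fit, and 615 without E3, 644 without F2, 660 without E2, 662 without E4 and 1703 without F1. Without C1, E3 and F3, left out after the results were seen, it was 540, and Nts (adjusted p = 0.293), Trem2 (0.313), Cx3cr1 (0.434), Ifit3 (0.216), Xbp1 (0.143) and Tmem97 (0.0695) were not called, while Cxcl10 was (0.00945).

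Microglia genes rose in injured wild-type spinal cord (4 SNI against 5 naive libraries). The complement gene C1qc went from 20.9 ± 2.08 to 56.5 ± 3.11 CPM (log2 fold change 1.43 ± 0.06, adjusted p = 3.74e-14) and Csf1r from 76.3 ± 5.2 to 158 ± 7.19 CPM (1.05 ± 0.05, adjusted p = 1.39e-13). Tmem119, a marker of resident microglia, went from 14.6 ± 0.739 to 33.2 ± 2.05 CPM (1.18 ± 0.07, adjusted p = 9.31e-12). The lysosomal gene Ctss (1.43 ± 0.06) rose with them. Of 14 microglia genes 13 rose (median 0.93, camera adjusted p = 1.48e-141, 2.77e-08 with an estimated correlation). Of 17 macrophage genes 12 rose (median 1.01, 8.63e-124 and 1.19e-06). Interferon response genes rose in 12 of 16 (15 when adjusted over the list alone, median 1.07, 1.54e-31 and 0.00301). The clearest were Usp18 (1.93 ± 0.23, adjusted p = 3.21e-06), Ifi44 (2.31 ± 0.28) and Irf7 (1.72 ± 0.22). Of 11 chemokine and cytokine genes 6 rose, with 1 lower when adjusted over the list alone (median 0.84, 6.08e-12 and 0.0017). They included Ccl7 (0.154 ± 0.0538 to 1.74 ± 0.595 CPM), Cxcl10 (0.276 ± 0.0791 to 1.39 ± 0.507 CPM) and Ccl12 (2.01 ± 0.33). Astrocyte genes rose in 2 of 11 (4 when adjusted over the list alone, 4.25e-05 and 0.0295), namely Gfap from 1056 ± 129 to 1758 ± 81.8 CPM (0.74 ± 0.07, adjusted p = 2.47e-06) and Aqp4 (0.24 ± 0.05).

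Transcripts of the axon injury program also appeared in the injured wild-type cord. Sprr1a went from 0.183 ± 0.182 to 38.5 ± 12.9 CPM (adjusted p = 2.02e-08), Atf3 from 0.88 ± 0.378 to 23.9 ± 9.28 CPM (4.75 ± 0.36, adjusted p = 5.68e-07) and Anxa10 from 0.0782 ± 0.037 to 3.77 ± 1.46 CPM. Gpr151, a receptor gene of injured neurons (2.72 ± 0.30), and Ecel1 (0.51 ± 0.06) rose too. Of 24 neuronal injury genes 12 rose, 18 when adjusted over the list alone (median 0.31, 1.3e-36 and 3.8e-05 with an estimated correlation). Scn10a, a sodium channel of nociceptors, ranged only from 0 to 1.5 CPM in injured cord. Pdyn, the prodynorphin gene of dorsal horn neurons, rose (27.3 ± 1.8 to 39.6 ± 4.11 CPM, 0.54 ± 0.07, adjusted p = 2.6e-05), with no other of 7 opioid genes passing. Scn9a (0.79 ± 0.11, adjusted p = 9.47e-05) and Tac1 (0.27 ± 0.07) were the 2 of 13 nociceptor genes that rose. The checkpoint gene Lag3 (2.17 ± 0.14, adjusted p = 6.95e-11) and the protease inhibitor gene Serpina3h (2.26 ± 0.26) were among the largest rises. Falls were few and small, such as the acetylcholinesterase gene Ache (-0.24 ± 0.04, adjusted p = 0.000423) and Slc13a3 (-0.40 ± 0.07). Plekhd1 (-0.29 ± 0.06), Ttc39a (-0.35 ± 0.08) and Hs6st3 (-0.40 ± 0.11) also fell. Psmb8 (0.92 ± 0.13) and B2m (0.50 ± 0.09) rose in the antigen presentation list, with 2 of 12 up (5 when adjusted over the list alone, adjusted p = 0.000105, 0.0945 with an estimated correlation).

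In total 543 of 18843 genes changed in injured wild-type cord, 492 up and 51 down, with 174 rises and 1 fall of more than 2-fold and 2098 genes at unadjusted p under 0.05 against 942 by chance. Respiratory chain (0.0189), potassium channel (0.0434), blood (0.0434) and general neuronal lists (0.0486) were called lower without any member that passed, at medians of -0.05, -0.05, -0.51 and -0.09. Their adjusted p was 0.688, 0.408, 0.597 and 0.597 with an estimated correlation. Rises shared with wild-type DRG numbered 307, such as Sprr1a, Atf3, Csf1r and C1qc, where 60.2 would be shared by chance if the tissues were independent.

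**Figure D3:**
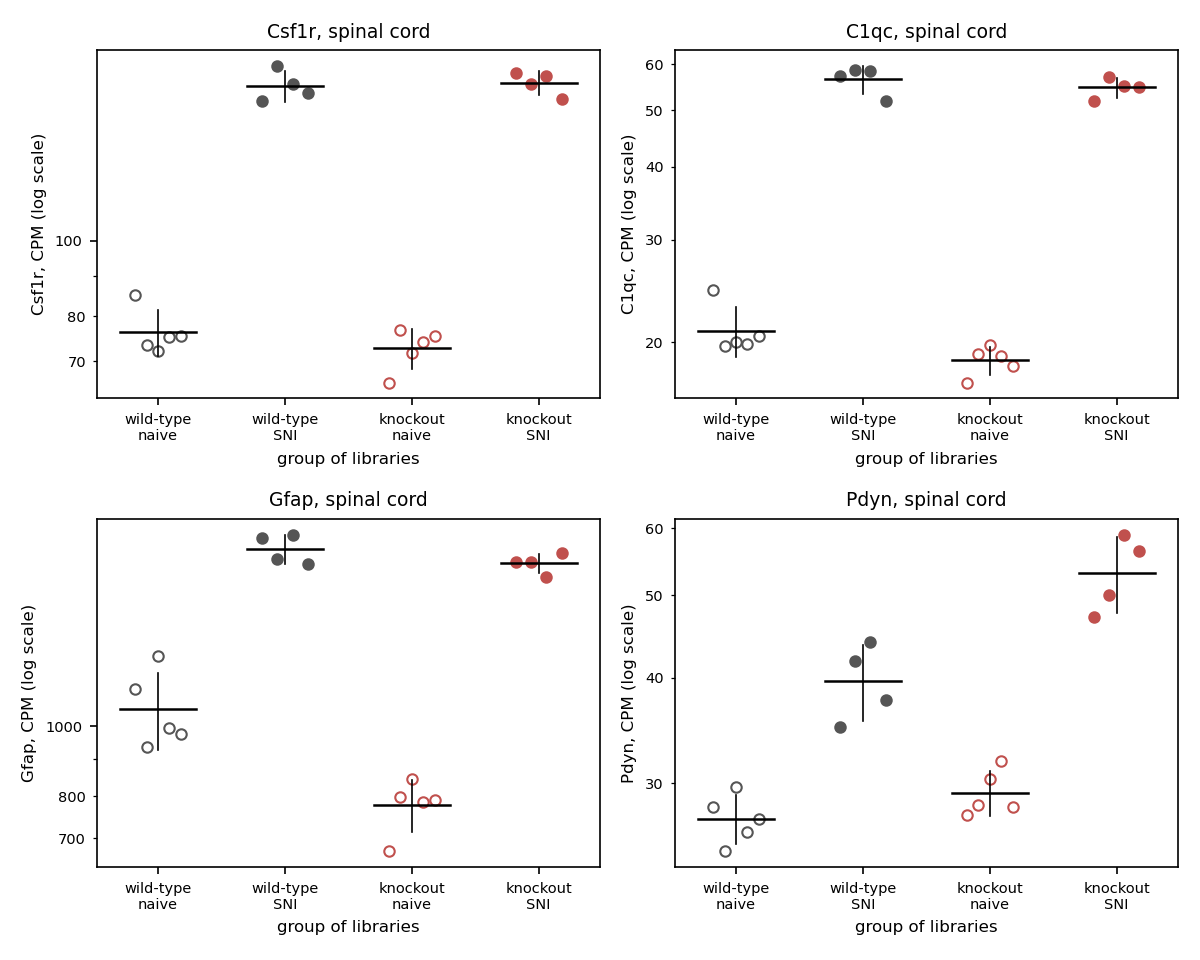
Csf1r, C1qc, Gfap and Pdyn in spinal cord libraries, in CPM on log scales, by group. Points are libraries, horizontal bars are means and vertical bars standard deviations, and Csf1r rises from 76.3 to 158 CPM in wild type and from 72.7 to 160 CPM in knockout.

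In knockout spinal cord injury raised microglia and axon injury genes too (4 SNI against 5 naive libraries). C1qc went from 18.6 ± 1.04 to 54.7 ± 2.18 CPM (1.56 ± 0.06, adjusted p = 8.15e-15), Csf1r from 72.7 ± 4.34 to 160 ± 5.47 CPM (1.13 ± 0.05, adjusted p = 2.06e-14), and Tmem119 (1.19 ± 0.07) and Ctss (1.58 ± 0.06) rose. Sprr1a went from 0.0445 ± 0.044 to 38.9 ± 10.9 CPM, Atf3 from 0.862 ± 0.29 to 26.6 ± 6.72 CPM (4.94 ± 0.36) and Anxa10 from 0.0634 ± 0.0411 to 6.03 ± 3.02 CPM. Gpr151 (2.99 ± 0.30), Ecel1 (0.72 ± 0.06), Mettl7a3 (2.89 ± 0.28) and Serpina3h (2.48 ± 0.24) rose. Gfap went from 778 ± 63.9 to 1678 ± 50.8 CPM (1.11 ± 0.07, adjusted p = 8.31e-09) and Pdyn from 29.2 ± 1.8 to 53.2 ± 5.49 CPM (0.86 ± 0.07, adjusted p = 1.21e-08). All 14 microglia genes rose (median 1.13, camera adjusted p = 5.72e-145, 2.15e-08 with an estimated correlation). So did 12 of 17 macrophage genes (13 when adjusted over the list alone, 3.12e-113 and 1.46e-06) and 14 of 24 injury genes (18 when adjusted over the list alone, 2.93e-45 and 7.43e-06). Of 11 chemokine and cytokine genes 6 rose (1.08e-08 and 0.00469), such as Ccl7 (2.81 ± 0.38), Tgfb1 (1.0 ± 0.16) and Cxcl10 (0.135 ± 0.0718 to 0.746 ± 0.162 CPM). Further, 2 of 11 astrocyte genes rose (4.7e-09 and 0.00397).

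Of 16 interferon response genes 7 rose in knockout cord (14 when adjusted over the list alone), such as Usp18 (1.52 ± 0.24), Oasl2 (0.86 ± 0.16) and Ifi44 (1.41 ± 0.27), with adjusted p = 4.83e-12 and 0.0564 with an estimated correlation. Of 13 nociceptor genes 3 rose (4 when adjusted over the list alone, 0.00184 and 0.0207), Scn9a (0.86 ± 0.11), the glial factor receptor gene Ret (0.55 ± 0.08) and Tac1 (0.34 ± 0.07). Libraries E6 and F6 held 1.32 and 1.5 CPM of Scn10a, a gene of DRG neurons, against 0 and 0.0439 CPM in E8 and F8, and had the highest nociceptor scores (3.073 and 2.867). Without A5, B5, E6, F5 and F6, left out after the results were seen, the nociceptor median went from 0.236 to 0.0763 and the list stayed called. Psmb8 (0.99 ± 0.13), B2m (0.54 ± 0.09) and Tap1 (0.62 ± 0.16) rose among 12 antigen presentation genes (0.000612, 0.132 with an estimated correlation). Falls were in Syt1 (-0.16 ± 0.03) and the immediate early gene Egr3 (-0.58 ± 0.14, adjusted p = 0.0105). The purine receptor gene P2ry1 (-0.35 ± 0.08), Aqp6 (-0.60 ± 0.17), Npc1l1 (-0.52 ± 0.14), Pole (-0.38 ± 0.11) and Ankfn1 (-0.37 ± 0.08) fell too. Potassium channels were called lower as a list (1 of 15 lower, 5 when adjusted over the list alone, adjusted p = 0.00483). Skeletal muscle (median -2.27, 0.032) and Schwann cell genes (-0.26, 0.0455) were called lower too, and opioid genes higher (0.053, 0.0195). With an estimated correlation the adjusted p was 0.161 for potassium channels, 0.629 for skeletal muscle, 0.722 for Schwann cell and 0.138 for opioid genes. In all, 833 genes changed, 715 up and 118 down, with 242 rises and 1 fall of more than 2-fold and 2726 at unadjusted p under 0.05. Without A5, B5, E6, F5 and F6 the count was 439, 433 up and 6 down.

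Rises were shared by both genotypes in cord for 416 genes (18.7 by chance), among them C1qc, Csf1r, Gfap and Sprr1a, and falls for 7 (0.319 by chance). The slope was 0.984, the correlation 0.910, and 93.9% of 953 genes had the same sign. No cord gene differed in its injury response between genotypes over all genes, while 3 of 5 blood, 2 of 7 opioid and 1 of 11 astrocyte genes moved higher with injury in knockout than in wild type when adjusted over the list alone. Unadjusted p was under 0.05 for 1150 genes in edgeR, and DESeq2 and limma called 0 genes as well, with 1088 and 1228 at unadjusted p under 0.05. Of the 27 lists, 13 were called by camera for the interaction, among them microglia (median 0.13, adjusted p = 0.000826), interferon response (-0.40, 0.000826), neuronal injury (0.12, 0.000865) and motor neuron genes (0.59, 0.00124). So were T cell (0.72, 0.00198), nociceptor (0.31, 0.0191), astrocyte (0.08, 0.0206), macrophage (0.12, 0.023) and opioid genes (0.12, 0.0319). The same 9 lists had adjusted p = 0.261, 0.39, 0.261, 0.335, 0.261, 0.261, 0.264, 0.563 and 0.261 with an estimated correlation. General neuronal and blood (both 0.000526, then 0.261), skeletal muscle (0.000865, then 0.354) and respiratory chain genes (0.00389, then 0.563 with an estimated correlation) were the other 4.

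Naive knockout cord differed from naive wild-type cord mostly by small amounts (5 against 5 libraries). The astrocyte genes Gfap (778 ± 63.9 against 1056 ± 129 CPM, -0.44 ± 0.07, adjusted p = 0.000304) and S100b (-0.48 ± 0.06) were lower and Glul higher (0.16 ± 0.04), in a list of 11 with 3 higher and 3 lower that was not called (0.429). The myeloid genes Tyrobp (-0.48 ± 0.08, adjusted p = 8.9e-05), Cd14 (-0.56 ± 0.12) and C1qb (-0.31 ± 0.07) were lower, while the microglial receptor gene Fcrls was higher (0.65 ± 0.11, adjusted p = 0.000535). The mu opioid receptor gene Oprm1 was higher (9.31 ± 1.34 against 7.2 ± 1.14 CPM, 0.37 ± 0.11, adjusted p = 0.0229), opposite to naive DRG. The DRG difference was not called with the blood score in the fit, nor in injured DRG. The NMDA receptor gene Grin2b (0.30 ± 0.06, adjusted p = 0.0016), Itpr2 (0.20 ± 0.04) and Ank2 (0.14 ± 0.03) were higher. Hemoglobin genes were lower, with Hba-a1 at 53.8 ± 6.78 against 122 ± 44.8 CPM (-1.18 ± 0.23, adjusted p = 0.003), and Ighm (-1.23 ± 0.23) and Ifit3 (-1.01 ± 0.20, adjusted p = 0.00231) were lower too. Of 19 respiratory chain genes 8 were lower (14 when adjusted over the list alone, median -0.11), such as Cox7b (-0.44 ± 0.09), Atp5g1 (-0.24 ± 0.05) and Cox5a (-0.21 ± 0.04). Of 10 oligodendrocyte genes 3 were lower, Olig1 (-0.27 ± 0.06), Cnp (-0.11 ± 0.03) and Mbp (-0.16 ± 0.06).

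Respiratory chain (adjusted p = 0.000266), blood (4 of 5 lower, median -1.06, 0.00197), macrophage (5 of 17 lower, 7 when adjusted over the list alone, median -0.23, 0.0166) and potassium channel lists (4 higher and 1 lower of 15, 7 and 1 when adjusted over the list alone, median 0.10, 0.045) were called in naive cord. All 4 had adjusted p = 0.87 with an estimated correlation. In the exact permutation test of list scores, macrophage genes had adjusted p = 0.2, and respiratory chain, blood and potassium channel genes 0.0857 each. Kcnt1 (0.29 ± 0.04) and Cacna2d1 (0.20 ± 0.04), the gene of the gabapentin target, were higher. Large single differences were in Xdh, a purine enzyme gene (81.1 ± 4.46 against 14.1 ± 5.42 CPM, 2.52 ± 0.27, adjusted p = 2.14e-05), and the myeloid receptor gene Cd300lf (2.27 ± 0.262 against 0.469 ± 0.255 CPM). Others were Cwc22 (3.18 ± 0.49), Il1f9 (2.0 ± 0.30) and Fam227b (0.283 ± 0.257 against 12.2 ± 4.93 CPM). Hmga1b (0.58 ± 0.317 against 24.1 ± 6.2 CPM), Vcp-rs (0.784 ± 1.55 against 194 ± 10.2 CPM) and Got2-ps1 (6.56 ± 0.47 against 0.0859 ± 0.0814 CPM) differed as in DRG. In all, 3718 genes differed, 1845 higher and 1873 lower in knockout, with 147 and 227 more than 2-fold and 6251 at unadjusted p under 0.05. With the blood score in the fit the count was 653, and 2315 without the 5 cord libraries that held over 0.5 CPM of Scn10a.

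Injured knockout cord held more prodynorphin than injured wild-type cord (4 against 4 libraries), with Pdyn at 53.2 ± 5.49 against 39.6 ± 4.11 CPM (0.42 ± 0.07, adjusted p = 8e-04). Oprm1 (0.49 ± 0.13, adjusted p = 0.018), Fcrls (26.9 ± 1.08 against 13.7 ± 2.45 CPM, 0.98 ± 0.12, adjusted p = 1.4e-05), P2ry12 (0.29 ± 0.06), the glutamate transporter gene Slc1a2 (0.26 ± 0.06) and Grin2b (0.29 ± 0.07) were higher as well. Ccl7 (0.857 ± 0.246 against 1.74 ± 0.595 CPM, -1.02 ± 0.28, adjusted p = 0.0257), the Fc receptor gene Fcgr1 (-0.43 ± 0.11), Tyrobp (-0.27 ± 0.08), C1qb (-0.23 ± 0.07) and Ifit3 (-0.90 ± 0.20, adjusted p = 0.0127) were lower. Interferon response genes (1 of 16 lower, median -0.44) and Schwann cell genes (1 of 11 lower, 2 when adjusted over the list alone, median -0.66) were called at adjusted p = 0.00458, with 0.714 each with an estimated correlation. Xdh (1.97 ± 0.29), Cd300lf (2.47 ± 0.24), Cwc22 (2.42 ± 0.54) and Ccl19 (0.611 ± 0.308 against 5.99 ± 0.454 CPM) differed as in naive cord or DRG, and Hist2h2aa2 was higher (1.34 ± 0.24). In all, 1179 genes differed, 555 higher and 624 lower, with 101 and 179 more than 2-fold and 3703 at unadjusted p under 0.05. Without 5 cord libraries that held over 0.5 CPM of Scn10a the count was 453.

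Genotype differences recurred across injury and tissue. In cord 395 genes, such as Xdh and Cwc22, were higher and 513, such as Vcp-rs, lower in knockout in both naive and injured libraries, against 54.3 and 62 by chance. Between tissues, 143 were higher and 219 lower in both injured DRG and injured cord (12.7 and 15.6 by chance). In naive libraries 387 were higher and 685 lower in both tissues (242 and 279 by chance), and 401 had opposite calls, Oprm1 among them. No chance count was made for the opposite calls, so they were not shown to exceed chance. After injury, knockout DRG and knockout cord shared 457 rises (105 by chance) and 46 falls (15.9 by chance). The chance counts between tissues treat the tissues as independent. DRG and cord libraries shared animal numbers, and wild-type libraries of the same number deviated together (r = 0.13 to 0.253 over all genes). Overlap from differences between animals alone could therefore be larger than these chance counts.

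**Figure D4:**
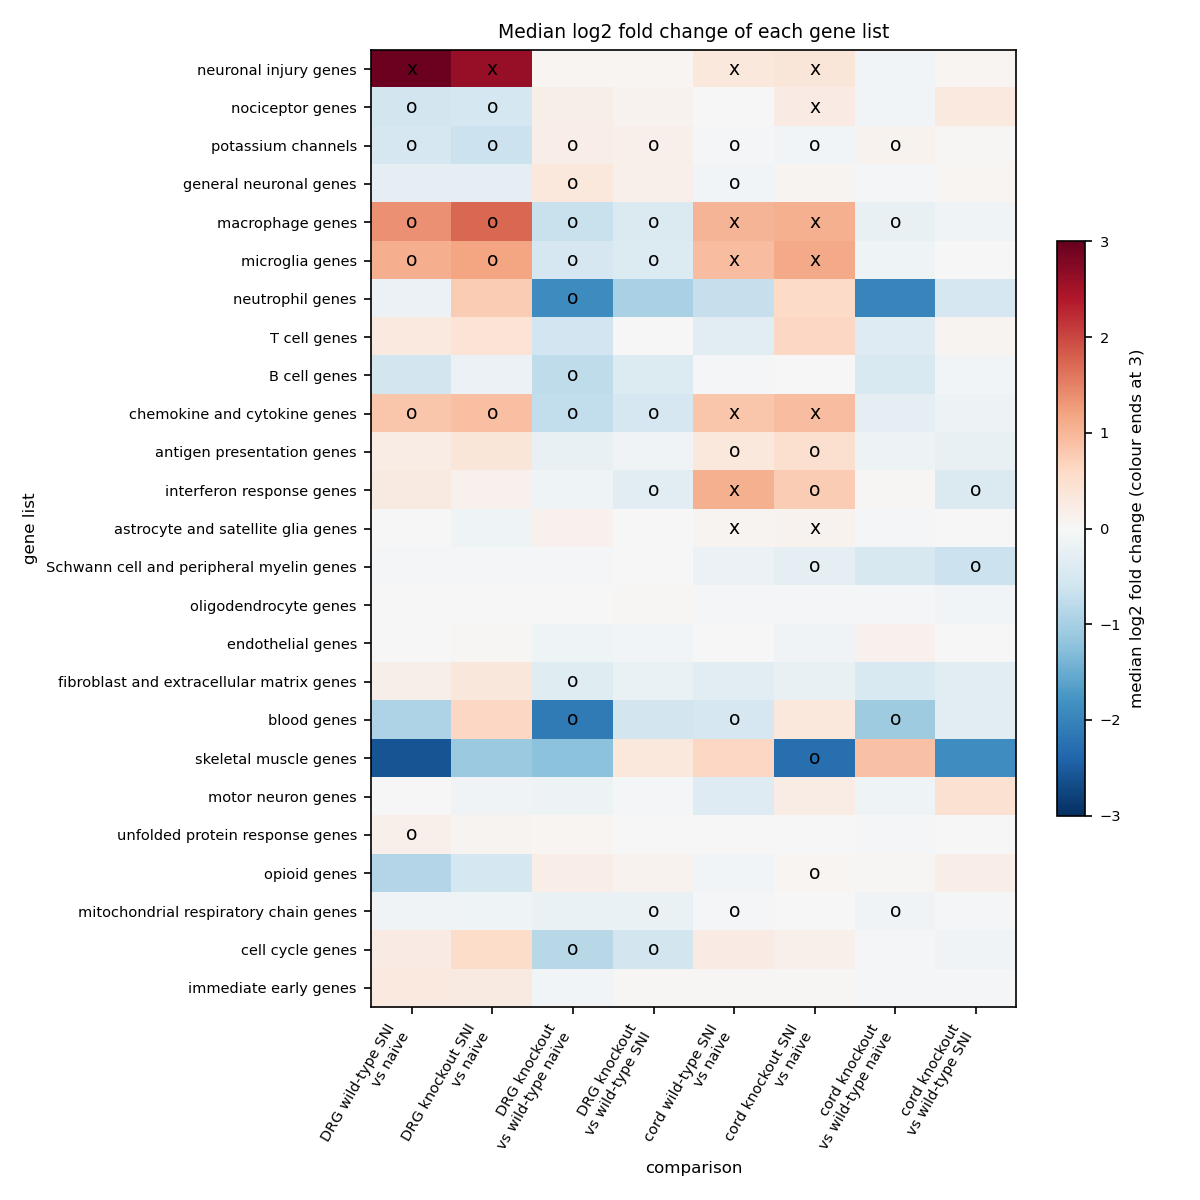
Median log2 fold change of gene lists (vertical) in 8 comparisons (horizontal), as colour. A letter marks the lists called by camera, x where the call held with an estimated correlation and o where it did not, and the neuronal injury list at 2.94 in wild-type DRG is the strongest.

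Of the 78 list calls over all 10 comparisons, 14 held with an estimated correlation. They were the neuronal injury list in each of the 4 injury comparisons, the microglia, macrophage, chemokine and cytokine and astrocyte lists in cord of both genotypes, and the interferon response list in wild-type and the nociceptor list in knockout cord. None was a genotype comparison.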

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

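The alternatives without C1, E3 and F3 and with the blood score, and the regrouping of DRG libraries, were chosen only after the results were seen.

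The response to injury differed between genotypes for 5 DRG genes by the interaction test of edgeR. Gal rose further in knockout (difference in log2 fold change 1.05), which encodes galanin, a peptide that injured sensory neurons make and that can inhibit or excite pain pathways depending on its receptor. Of the other genes, Cyp4b1 (1.33), C130060K24Rik (3.46, from 0.0678 CPM in naive knockout) and Flrt3 (0.429) also rose further in knockout, and 9430062P05Rik (-1.50) rose in wild type alone. Regrouping the DRG libraries gave up to 4 called genes in the highest of the other splits, and 1 of the 100 splits, the real split, gave 5. The regrouping decided nothing for this count, because the other splits carry the genotype difference as spread within groups. Gal stayed called without A2 and A4 (adjusted p = 0.0058), with the blood score in the fit (0.000751), without C1, E3 and F3 (0.000923) and in DESeq2 (2.98e-15). Flrt3 was not called without A2 and A4 (0.281), and neither Cyp4b1 nor Flrt3 was with the blood score (0.0708 each).

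Single libraries stood far from the rest of their group in 3 of the 96 groups of values tested, over 12 measures, where chance gives about 1 in 20 groups. The neutrophil score was 1.655 in F8, an injured knockout cord library, against 0.922 to 1.026 in the others, and 2.64 in A7, a naive wild-type cord library, against 1.159 to 1.585. F8 and A7 also had the highest blood scores of their groups, 4.471 and 5.423. The chemokine and cytokine score was 1.956 in A5, a naive wild-type cord library, against 1.784 to 1.824. Fewer libraries stood apart than chance would give, and no DRG library was among them. The test looks for 1 library alone, so it could not flag a pair such as E3 and F3 of injured wild-type DRG. Those differed from E1 and F1 by a mean chi-square per gene of 52.09 to 66.63. It was 8.574 between E1 and F1 and 12.95 between E3 and F3.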

How the results depend on the processing

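Tests without C1, E3 and F3, without A5, B5, E6, F5 and F6, and with the blood score as a covariate were chosen only after the results were seen. Without each library in turn injury counts ran from 4349 to 5061 in wild-type and 4669 to 5432 in knockout DRG, and from 460 to 562 and 617 to 832 in cord. With only its own groups in the fit wild-type DRG had 3216, and knockout DRG 7321. Of 416 named calls, 416 stayed called in the same direction with RLE factors. With DESeq2 406 of 413 did, while 7 were no longer called and 0 changed direction. No longer called were 39 of 416 without the filter, 31 of 413 with only the groups compared and 17 of 416 with limma-trend. The same held for 26 of 153 without A2 and A4 and 9 of 202 with the letter as a block. Over each library left out in turn, 371 of 3838 were no longer called. With the blood score 102 were no longer called and 4 changed direction. Of 78 list calls, 64 were lost with an estimated correlation. In the exact permutation test of list scores, 18 of 23 list calls between genotypes were lost. In injured libraries that test could hardly keep a call, so losses there decided little. Lists at its smallest p, 0.0286, had adjusted p = 0.331 in DRG (chemokine and cytokine genes) and 0.129 in cord (Schwann cell genes).

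Genotype counts depended on single libraries in DRG. In naive DRG the count of 5506 ran from 3032 without C1 to 6638 without B1, with 3248 without A2 and 3084 without A3, and was 2626 without A2 and A4 and 532 with the blood score. In injured DRG the count of 994 was 649 with only its own groups, 540 without C1, E3 and F3, 615 without E3, 644 without F2, 660 without E2, 662 without E4 and 1703 without F1. The cause was not tested. The interaction count of 5 was 25 with DESeq2, 19 with all 36 libraries, 3 with the letter of the title as a block, 2 without A2 and A4 and 1 with the blood score, and 5 without C1, E3 and F3, of which 1 was shared. It was 1 without F2, 2 without A4, 3 without A2, A3, E2, E4 or F4, and 7 without B1.

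In cord, leaving out A5, B5, E6, F5 and F6 gave 439 for injury in knockout, 2315 for genotype in naive and 453 in injured libraries. The blood score gave 653 in naive cord. Single libraries moved naive cord from 2525 to 3900, injured cord from 825 to 1102 and left the interaction at 0. The cause was not tested. In naive cord limma on the authors' normalised values called 1394 genes higher and 2650 lower (34.5% higher, against 49.6%). The DRG slope, correlation and shared sign were 0.923, 0.887 and 85.3% without C1, E3 and F3, and the cord slope was 0.760 without its 5 libraries. Single libraries moved the slope from 0.954 to 0.997 in DRG and 0.885 to 1.006 in cord.

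With the blood score, these naive DRG values changed sign: Camp 0.12, Cd79b 0.39, Pecam1 0.012, Itpr2 0.056, and the list medians of neutrophil (0.15), B cell (0.64) and matrix genes (0.14). Microglia (-0.099) and blood medians (-0.013) kept their sign while camera turned their direction. In the DRG interaction the medians of general neuronal (0.085), macrophage (-0.14), neutrophil (-0.52) and blood genes (-0.00594) changed sign. Without C1, E3 and F3 potassium channels in injured DRG went to -0.026.

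Letters did not pair libraries. Knockout and wild-type libraries with the same letter deviated together at a mean correlation of -0.00602 in DRG (17 pairs, -0.141 to 0.23) and 0.00454 in cord. Genotype counts with the letter as a block were 5137 and 884 in DRG and 3376 and 1074 in cord. The mean chi-square per gene between libraries of a group was at least 2.76 times sampling noise, and tests at lower depth were not made. At a log2 change of 0.5, 16.4% of simulated interactions were called in DRG and 64.6% in cord, as rough rates from a single draw each.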

Other observations

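All tests of explanations in this part, apart from the regroupings of cord libraries, were chosen only after the results were seen.

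Lymphocyte, matrix and peripheral nerve genes moved in smaller sets. In naive DRG the class II genes H2-Eb1 (5.76 ± 5.78 against 33.5 ± 25.9 CPM) and Cd74 (-0.81 ± 0.29) and the T cell gene Cd4 (-1.24 ± 0.30) were lower in knockout. In naive cord H2-Aa (-0.97 ± 0.30) was lower, as were Fbln5 (-0.47 ± 0.11), Ncmap (-0.77 ± 0.24) and Dhh (-0.90 ± 0.30) of the Schwann cell and peripheral myelin list. That list was not called there (3 of 11 lower, camera adjusted p = 0.0627). The vessel gene Flt1 was higher in naive knockout cord (0.27 ± 0.06). After injury the protease inhibitor gene Timp1 rose in cord of wild type (1.08 ± 0.30) and knockout (2.17 ± 0.31, adjusted p = 3.54e-05), and Trbc2, a T cell receptor gene, rose in knockout DRG (1.89 ± 0.39) and cord (1.23 ± 0.28). The axon genes Tubb3 (0.30 ± 0.07) and Stmn2 (0.30 ± 0.08) rose in injured knockout cord.

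Some genotype differences recurred in both tissues and in both naive and injured libraries, for 305 of 17849 genes (113 higher and 192 lower), with 51 pseudogenes (16.7% against 3.93% of genes tested). A mixed or different genetic background may explain part of them, since the shared genes of DRG and cord libraries with the same wild-type animal number deviated together (mean r = 0.646, 0.496 to 0.745) more than in any of 100 matched gene sets (highest 0.517), and far more than libraries of other numbers (at most 0.0924). Knockout numbers showed less of this (mean r = 0.194, matched sets up to 0.462). An effect of the knockout itself cannot be told apart from background, because 0 libraries carried labels that part them.

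Blood, immune and cell cycle genes were lower in naive knockout DRG, and more blood or marrow in the wild-type libraries may explain part of it. Across 18 libraries, within groups, the neutrophil score followed the blood score (r = 0.935, permutation p adjusted over 7 relations 7e-05, rho = 0.924, r = 0.914 without C1 and A2), and with the blood score in the fit the neutrophil median went from -1.88 to 0.147. For macrophage genes (r = 0.575, permutation p = 0.0357, adjusted 0.0417, rho = 0.575, r = 0.546 without C1 and A2) the median went from -0.67 to -0.178, which passed a bound set after the result was seen only narrowly and left a difference. Knockout scores of at most 5.72 all lay below wild-type scores of at least 6.13, so this fit extrapolates and could also remove a true genotype effect. In injured DRG the chemokine list stayed called with the blood score in the fit (median -0.405, camera adjusted p = 0.000705). Without that score it was not called with an estimated correlation (adjusted p = 0.844). Within groups the chemokine score also followed the blood score (r = 0.623, permutation p adjusted over 7 relations 0.0315). Blood was therefore not excluded for these genes. A smaller share of neurons in wild type, with other cells raised alike, was not seen in naive DRG. Schwann cell genes held level there (median -0.0239, lower quartile -0.0869 against an upper quartile of -0.543 for macrophage genes). Fewer neuronal transcripts beside more blood could not be excluded this way, since general neuronal genes were higher in naive knockout (median 0.31).

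Axon injury genes of sensory neurons rose in injured cord, where their cells do not lie. DRG tissue in the cord samples could not account for most of the Sprr1a reads. At the share read from Scn10a it would bring a median of 0.313% of them, 4.72% at most. Some DRG tissue in the cord samples was not excluded, and the other injury genes were not tested this way. Injured motor neurons, which also switch on Sprr1a and Atf3, could be the source, since Sprr1a followed the motor neuron score over the 8 injured cord libraries (r = 0.856, exact permutation p = 0.00538, rho = 0.881, r = 0.803 without F5 and F7, 1 relation tested). That would need ventral horn in samples described as dorsal. All 6 motor neuron genes passed the filter in cord, and Chat ranged from 6.38 to 15.3 CPM over the injured cord libraries. Whether ventral horn was in the samples was not tested.

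Regrouping libraries asked whether the called counts could arise by chance. For injury in wild-type DRG 1 of the 100 splits, the real split with 3216 genes, gave as many (next 1833), and the same held in knockout DRG (7321, next 3287) and between genotypes in naive DRG (5892, next 3359). In injured DRG 1 of the 35 splits, the real split with 649 genes, gave as many (next 2), as in injured cord (1316, next 2). In cord 1 of the 100 splits gave as many for injury in wild type (450, next 62) and knockout (887, next 358) and for genotype in naive libraries (3125, next 17). Chance alone was thus unlikely for each count taken singly, but it was not excluded. The real split could be no rarer than 1 of 35 or 1 of 100, without adjustment over the comparisons. Other splits of DRG libraries still gave up to 3359 genes. For the cord interaction the regrouping decided nothing, since its 0 genes were reached by 100 of the 100 splits by necessity, with up to 7 in other splits.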
